A study of Mus musculus with 8 samples.

How the data were processed

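RNA was measured by sequencing in 8 libraries of mouse bone marrow cells sorted as lineage-negative and CD127-positive, 4 from wild-type (WT) and 4 from Trerf1 knockout (KO) marrow, with the group of each library taken from its title and genotype label. CD127 is the interleukin 7 receptor alpha chain, carried by early lymphoid progenitors and by innate lymphoid cells and their precursors. Per the labels' protocols, RNA was purified with a column kit for small samples and 200 ng of total RNA went into a low-input cDNA library kit that does not mark strand. The labels number the libraries 1 to 4 in each group and do not say whether these are separate animals, so p-values measure the spread between these libraries.

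The authors deposited, for each library, a table of whole-number read counts per gene, which per the file headers came from featureCounts 1.6.4 run on alignments with duplicates marked. The header's command line shows only an annotation, an output name and 4 threads. Under the defaults that leaves in place, reads of both strands were counted together, mates of a pair were counted singly, marked duplicates were kept, and reads that mapped to several places or overlapped several genes were left out. The authors also deposited RSEM expected counts per gene for each library, which are estimates of fragments and need not be whole; RSEM 1.3.1, the aligner STAR 2.6.0a and Picard 2.19 are named in the submitters' processing notes. Counts summed to 3.67 to 4.00 times the expected counts, and 59.9% to 76.6% of counts between 1 and 100 were even. The cause of the ratio was not tested. The notes name build mm10, whereas the annotation path in the header of the count files names GRCm39. Of 52057 nuclear genes shared with the GENCODE M21 annotation of GRCm38, 1443 (2.77%) had the same start and end as in the count files, and coordinates below are those of the count files, taken as GRCm39.

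The count files list 53647 gene identifiers, of which 52093 (97.1%) were matched to a symbol through the gene name table of the reference. Gene types were taken from GENCODE M21 by identifier. That annotation types Trerf1 as a processed transcript, so Trerf1 drops out where protein-coding genes alone were tested. Type TEC marks unspliced transcripts that still await experimental support.

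Counts of all 8 libraries were fitted with edgeR 4.0.16 in R 4.3.3: genes kept by filterByExpr, TMM scaling, quasi-likelihood F test of knockout against wild type with no covariate, and Benjamini-Hochberg adjustment with a threshold of 0.05. CPM values are TMM-scaled unless said otherwise, errors of CPM are SD, and errors of log2 fold changes are standard errors from that fit (size divided by the square root of F). Log2 CPM used a prior count of 3. Of the 38 gene lists, 37 with at least 5 tested members were tested with camera of limma 3.58.1 at a preset inter-gene correlation of 0.01, adjusted over the lists, and again with an estimated correlation and with fry. The other list, sex-linked genes, is given per library. The lists hold 697 genes apart from the sex-linked ones, of which 3 were not found among the symbols and 66 were under the count filter. Single values per library (Trerf1, principal component scores, shares of gene types) were compared by a two-sided exact permutation test over the 70 assignments of 8 libraries to groups of 4, whose smallest p is 0.0286. Principal components used the 2000 most variable genes. Genes starting within 10 Mb of Trerf1 were compared with all others by Fisher's exact test, two-sided.

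The lists, tests, alternatives and naming rule were set before the data were examined. The rule names Trerf1; up to 12 genes per direction past the threshold; where fewer than 5 passed, the 5 with the smallest p in that direction as values that did not pass; up to 4 members with the smallest p of each list that passed and 1 of some lists that did not; the sex-linked genes; and 3 genes near Trerf1. Gm and Rik symbols, receptor variable segments, ribosomal pseudogenes and mitochondrial genes are not named under it. Genes named outside it are said to be. A gene that the rule names is not reported here. Alternatives were RLE factors, library size alone, no filter, mean CPM of at least 1, DESeq2 1.42.0, limma-voom with library quality weights, the RSEM expected counts rounded to whole numbers, the replicate number as a block, Xist as covariate, 1 surrogate variable (sva 3.50.0), leaving out genes of immunoglobulins, haemoglobins, mitochondria and ribosomal proteins, an adjusted p of 0.1, a minimum log2 fold change of 1, 500 or all genes in the components, windows of 5 and 20 Mb, and each library left out. Further alternatives, chosen after seeing the data, left out WT4 and KO4 together, used the TEC share or depth class as covariate, or kept subsets of genes or libraries.

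The steps were tested on simulated data with the real means, dispersions and library sizes of knockout against wild type, 4 against 4. Of 100 genes changed 2-fold, edgeR recovered 72% over 15965 genes, and of 100 changed 4-fold it recovered 90%, with 4.71% of calls on unchanged genes. Limma-voom recovered the same shares with 3.57% of calls on unchanged genes, and DESeq2 recovered 81% and 95% over 16352 genes with 16.6%. With no change simulated, camera called 0 of 37 lists. With the G2 and M phase list raised 2-fold it called 1, with an adjusted p of 2.17e-05 under an estimated correlation. Each gene was drawn independently, so the simulated data hold no correlation between genes and no structure among libraries beyond their sizes. They therefore cannot show how often camera at the preset correlation calls unchanged lists whose genes vary together, as genes in the real libraries may. Nor can they show what share of real changes edgeR would recover in libraries that differ in other ways as well. No pair of libraries agreed within sampling noise: the chi-square of counts per degree of freedom was 21.3 for WT1 and KO1, 50.7 for WT2 and KO2, 29.6 for WT3 and KO3, and 48.7 for WT4 and KO4. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.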

Results

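Gene expression was measured in lineage-negative CD127-positive bone marrow cells of mice labelled wild type and Trerf1 knockout, 4 libraries per group. Trerf1 encodes a zinc finger transcription factor first described as a regulator of steroid hormone synthesis genes. The single question the labels pose is which genes differ between knockout and wild type. Total counts were 34541825, 63498254, 31109744 and 73414626 in WT1 to WT4 and 36184497, 32821991, 33157291 and 66515540 in KO1 to KO4. WT2, WT4 and KO4 were thus the 3 deeper libraries, and the other 5 are called the 5 shallower libraries below. In both groups the most abundant protein-coding transcripts included Ly6d, a surface marker of B-lineage-biased lymphoid progenitors, at 3481 ± 658 CPM in wild type and 4220 ± 682 CPM in knockout (SD, n = 4 each). Irf8, a transcription factor of dendritic and B lineages, stood at 3598 ± 818 and 3643 ± 403 CPM, and Dntt, the terminal transferase of lymphoid progenitors, at 1826 ± 712 and 1933 ± 784 CPM. Il7r, which encodes the sorted CD127, was at 324 ± 46.8 CPM in wild type and 354 ± 45.8 CPM in knockout. Other transcripts above Dntt included Psap at 5075 ± 1981 CPM in wild type and 5228 ± 733 CPM in knockout. Ctsb stood at 3029 ± 1049 and 3205 ± 374 CPM and Mpeg1 at 2264 ± 662 and 2310 ± 295 CPM. The genes picked here thus do not by themselves describe the sorted cells. Ly6d was named by rule. Irf8, Dntt, Il7r, Psap, Ctsb and Mpeg1 were named here for their level or their part in the sort, after their values were seen.

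Trerf1 was lower in 3 of the 4 knockout libraries than in any wild-type library, and in the library labelled KO4 it was at the level of WT4. The gene (ENSMUSG00000064043.16, chromosome 17, 47451801 to 47672883, plus strand, GRCm39 coordinates of the count files) gave 29.0, 32.1, 27.1 and 22.3 CPM in WT1 to WT4. It gave 13.4, 12.8 and 12.1 CPM in KO1 to KO3 and 22.1 CPM in the library labelled KO4, from 394 to 2116 counts per library. The means were 27.6 ± 4.09 CPM in wild type and 15.1 ± 4.72 CPM in knockout (SD, n = 4 each), or 54.7% of wild type. The log2 fold change was -0.87 ± 0.20 (SE), with an adjusted p of 0.999 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and an unadjusted p of 0.00151, rank 3 of 16352 genes. The two-sided exact permutation p was 0.0286, the smallest that 4 against 4 can give, and it was 0.0571 with library size alone or with RSEM expected counts, where the library labelled KO4 (22.1 and 20.6 CPM) lay above WT4 (21.3 and 18.4 CPM). With WT4 and KO4 both left out, an alternative chosen after seeing the data, the log2 fold change was -1.20 and the adjusted p was 0.0473. Which exons the allele lacks is not given in the sources used here, so counts outside a deleted part would remain in a knockout.

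Transcripts of the sex chromosomes parted the libraries in another way. Xist, the RNA of the inactive X chromosome, was at 531 CPM in WT1, 563 CPM in WT4, 447 CPM in KO1, 498 CPM in KO3 and 768 CPM in KO4, and at most 0.613 CPM in WT2, WT3 and KO2. The Y-linked genes had the opposite pattern. Ddx3y was at 82.9, 102 and 93.5 CPM in WT2, WT3 and KO2, and at 0.112 CPM or less in the other 5 libraries. Eif2s3y was at 137, 106 and 103 CPM, Kdm5d at 44.6, 43.0 and 41.5 CPM and Uty at 41.5, 38.6 and 33.1 CPM in the same 3 libraries. Each group therefore held libraries of both kinds, 2 with and 2 without Xist in wild type and 3 with and 1 without in knockout. Among the 5 libraries with Xist the Trerf1 log2 fold change was -0.69, and among the 3 without it was -1.23, a set with 1 knockout library. Among the 5 shallower libraries it was -1.13, and among the 3 deeper ones, again with 1 knockout library, -0.34. These sets were chosen after seeing the data, and none of the 4 values passed the threshold.

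**Figure D1:**
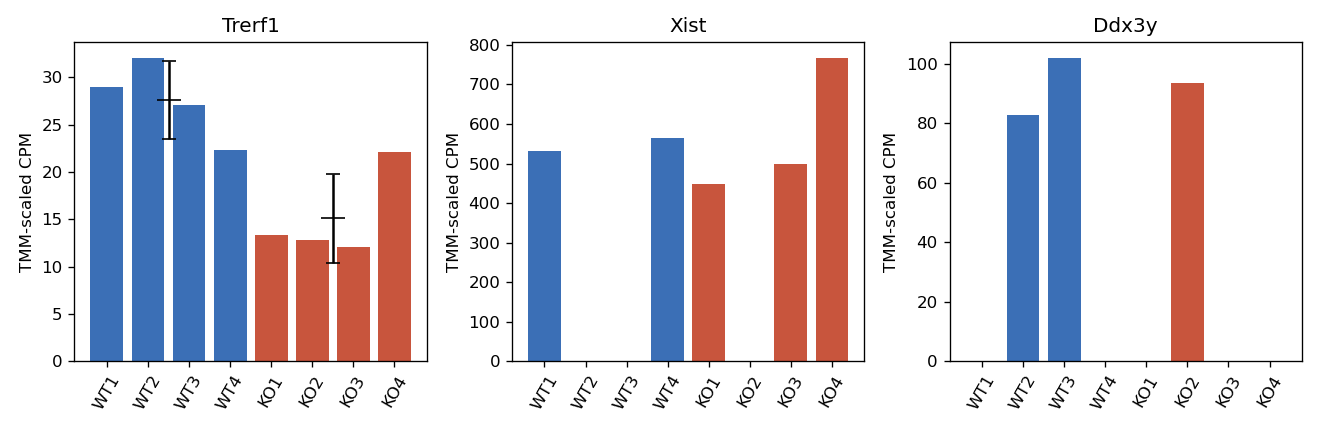
TMM-scaled CPM of Trerf1, Xist and Ddx3y (vertical axes, from 0) in each of the 8 libraries (wild type blue, knockout red); black marks in the Trerf1 panel are group means with SD. Trerf1 of the library labelled KO4, 22.1 CPM, stands beside 22.3 CPM in WT4 and above 12.1 to 13.4 CPM in KO1 to KO3.

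No gene passed the threshold in either direction. Of 16352 genes tested with edgeR, 0 were higher and 0 lower in knockout at an adjusted p under 0.05. An unadjusted p under 0.05 was found for 322 genes (170 higher, 152 lower), where uniform p-values would give 818. With 1 library left out this count ran from 168 without WT2 to 1016 without WT4, and it was 978 without KO4. DESeq2 and limma-voom with quality weights also called 0 genes, with 565 of 29987 genes (1.88%) and 891 of 16352 (5.45%) at an unadjusted p under 0.05. The biological coefficient of variation was 26.9%, and in simulated data of this size edgeR recovered 72% of 2-fold changes. Those data hold no structure among libraries beyond their sizes, so the share it would recover in the real libraries is not known. These counts rest on the label of KO4, in which Trerf1 was not low. With WT4 and KO4 both left out, 12 genes were lower and 0 higher in knockout. Besides Trerf1 these were C130089K02Rik, Gm47585, Gm40309, Gm38082, AC104328.1, Gm20696, Gm37675, Gm43696, A930001M01Rik, Gm47588 and 4933423P22Rik, named after their values were seen, and 7 of the 12 were TEC transcripts. All 12 were higher in the library labelled KO4 than in WT4 by CPM without scaling factors.

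Genes with the smallest p, none of which passed (each adjusted p 0.999, edgeR), included the following. On the higher side, Ifi214, an interferon-inducible gene of a family of near-identical copies that can share reads, was at 4.15 ± 0.828 CPM in knockout and 1.99 ± 0.320 CPM in wild type (log2 fold change 1.05 ± 0.24). Cym was at 2.19 ± 0.679 against 0.799 ± 0.311 CPM and Slc4a8 at 11.9 ± 1.35 against 8.35 ± 0.246 CPM. Tmem176a had log2 fold change 0.38 ± 0.10 at 76.6 CPM in wild type. On the lower side, Egr1, an immediate early transcription factor, was at 99.1 ± 9.96 CPM in knockout and 140 ± 25.8 CPM in wild type (log2 fold change -0.50 ± 0.13). Spata13 was at 86.8 ± 8.73 against 113 ± 12.2 CPM and Rap1gap2 at 6.03 ± 0.531 against 8.95 ± 0.894 CPM. Dock4 and Neb, both long genes, had log2 fold changes of -1.39 ± 0.41 and -2.00 ± 0.59 at 2.76 and 5.54 CPM in wild type.

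Of the 37 lists, 13 passed at the preset correlation, 10 with higher and 3 with lower expression in knockout, and 0 passed with an estimated correlation or with fry (smallest adjusted p 0.782 and 0.946). No list held a member past an adjusted p of 0.05, either over all genes or adjusted over the list alone. With 1 library left out the number of lists past the threshold ranged from 4 to 14: it was 6 without KO1, 4 without WT2, 6 without WT3 and 4 without the library labelled KO4. It was 4 in the 5 shallower libraries and 7 in the 5 libraries with Xist. With Xist as covariate, set in advance, 9 lists passed, among them 7 of the 13, and with the TEC share as covariate, added after seeing the data, 10 passed, among them 9 of the 13. The directions below include the library labelled KO4.

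**Figure D2:**
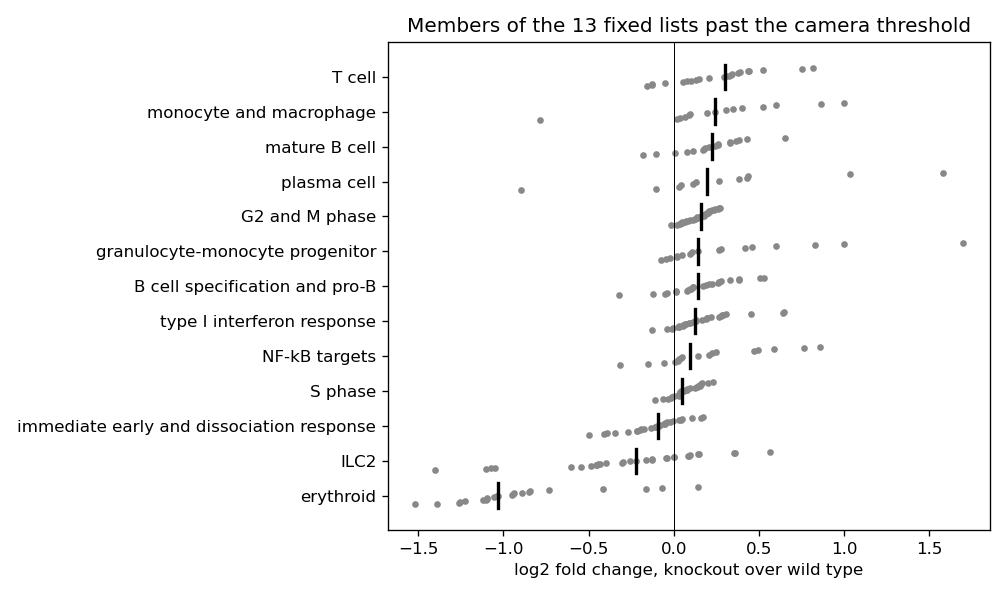
Log2 fold change of knockout over wild type (horizontal axis) for each tested member (grey points) of the 13 lists that passed camera at the preset correlation; black bars are list medians. The medians run from -1.03 for erythroid genes to 0.30 for T cell genes, and no single member passed.

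Genes of B cells, plasma cells and T cells lay higher in knockout by small amounts. Of 26 B cell specification and pro-B genes, 22 had higher estimates (median log2 fold change 0.14, adjusted p 0.00458, and adjusted p 0.782 with an estimated correlation). Cd79a, a signalling chain of the B cell receptor, was at 119 ± 17.8 CPM in knockout and 91.6 ± 6.41 CPM in wild type, and Lef1 at 17.4 ± 4.47 against 12.1 ± 0.538 CPM. Of 18 mature B cell genes, 16 had higher estimates (median 0.23, adjusted p 0.00516, and adjusted p 0.782 with an estimated correlation), among them Ccr7 at 88.7 ± 11.9 against 70.6 ± 9.26 CPM and Tnfrsf13c, the BAFF receptor, at 73.4 ± 5.17 against 58.5 ± 15.9 CPM. Of 12 plasma cell genes, 10 had higher estimates (median 0.20, adjusted p 0.0180, and adjusted p 0.782 with an estimated correlation). Jchain, which joins antibody multimers, was at 13.1 ± 2.6 against 6.46 ± 3.28 CPM and Slamf7 at 24.8 ± 3.28 against 18.3 ± 3.03 CPM, whereas Prdm1, the plasma cell regulator, had log2 fold change -0.90 ± 0.58. Of 22 T cell genes, 18 had higher estimates (median 0.30, adjusted p 0.00458, and adjusted p 0.782 with an estimated correlation). The T cell receptor chain genes Cd3g and Cd3d were at 10.2 ± 4.69 against 5.78 ± 1.57 CPM and 7.33 ± 3.80 against 4.35 ± 0.675 CPM. The pro-B and T cell lists lost their call without the library labelled KO4 (adjusted p 0.0636 and 0.101). Both calls were also lost with WT4 and KO4 left out together (adjusted p 0.0843 each), where the mature B and plasma cell lists passed (0.00496 and 0.0102). In the 5 shallower libraries all of these lists lost the call (adjusted p 0.152 for pro-B, 0.0799 for T, 0.111 for mature B and 0.0547 for plasma cells). The mature B and plasma cell lists lost theirs without any of KO1, WT2, WT3 and KO4 (adjusted p up to 0.162 and 0.391), and also with Xist as covariate (adjusted p 0.153 for both), and the mature B list turned direction in the 5 libraries with Xist.

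The lists of granulocyte-monocyte progenitors and of monocytes and macrophages also lay higher in knockout, whereas the neutrophil, eosinophil, basophil and dendritic cell lists did not pass. Of 17 granulocyte-monocyte progenitor genes, 14 had higher estimates (median log2 fold change 0.14, adjusted p 0.0102, and adjusted p 0.782 with an estimated correlation), and of 15 monocyte and macrophage genes, 14 did (median 0.24, adjusted p 0.0168, and again 0.782 as adjusted p with an estimated correlation). Csf1r, the macrophage growth factor receptor, and F13a1, coagulation factor XIII, are in both lists, at 54.9 ± 13.6 against 36.1 ± 12.4 CPM and 14.3 ± 9.68 against 7.17 ± 3.08 CPM. Prtn3, a granule protease, was at 20.4 ± 7.04 against 11.5 ± 5.34 CPM, and Ly6c2 at 282 ± 53.9 against 222 ± 57.2 CPM. The progenitor list lost its call without WT2 or the library labelled KO4 (adjusted p up to 0.105), and the monocyte list without KO1, WT2, WT3 or KO4 (adjusted p up to 0.315) and with Xist as covariate (adjusted p 0.0534).

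Genes of group 2 innate lymphoid cells (ILC2) and of erythroid cells lay lower in knockout. Of 31 ILC2 genes, 21 had lower estimates (median log2 fold change -0.22, adjusted p 0.0168, and adjusted p 0.782 with an estimated correlation). Il9r, the interleukin 9 receptor, was at 5.18 ± 3.10 CPM in knockout and 11 ± 4.01 CPM in wild type, the chemokine receptor gene Ccr8 at 4.88 ± 3.78 against 10.6 ± 3.59 CPM, Calca at 1.59 ± 1.05 against 4.24 ± 2.6 CPM and Klrg1 at 2.48 ± 0.482 against 5.14 ± 3.83 CPM. The list median relative to the mean of all libraries was 0.38 in the library labelled KO4 and -0.01 in WT4, against 0.41 in WT3 and -0.52 in KO2. The call was lost without KO1, WT2, KO2 or WT3 (adjusted p up to 0.435) and with the TEC share as covariate (adjusted p 0.412), and the direction turned in the 5 libraries with Xist (adjusted p 0.108). Of 23 erythroid genes, 22 had lower estimates (median -1.03, adjusted p 0.0168, and adjusted p 0.802 with an estimated correlation). Gata1, the erythroid transcription factor, was at 4.75 ± 3.93 against 8.81 ± 7.30 CPM and Alas2, a haem synthesis enzyme, at 2.77 ± 1.26 against 5.94 ± 5.92 CPM. Relative to the mean of all libraries, the erythroid median was 2.47, 1.01, -0.38 and -1.47 in WT1 to WT4. It was 1.42, 0.12, -1.51 and -0.92 in KO1 to KO4, so it fell with the library number in both groups, except from KO3 to KO4. With the replicate number as block, camera at the preset correlation gave an adjusted p of 1.78e-06. Without WT1 the direction turned (adjusted p 0.872). The call was also lost without WT2, KO3 or KO4, and with Xist as covariate (adjusted p 0.0534). Erythroid cells are among those that lineage depletion removes.

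Cell cycle genes lay slightly higher in knockout. Of 36 G2 and M phase genes, 35 had higher estimates (median log2 fold change 0.16, adjusted p 0.000270, and adjusted p 0.802 with an estimated correlation), with Ccnb1, the mitotic cyclin, at 176 ± 31 CPM in knockout and 146 ± 18.5 CPM in wild type and Tpx2, a spindle factor, at 238 ± 37.5 against 206 ± 20.2 CPM. The call was lost without KO2 or WT4 (adjusted p up to 0.230), and it was also lost with the TEC share as covariate (adjusted p 0.114). Of 32 S phase genes, 25 had higher estimates (median 0.05, adjusted p 0.0168, and adjusted p 0.802 with an estimated correlation), with Rrm2, a ribonucleotide reductase subunit, at 587 ± 56.3 against 523 ± 34.8 CPM. This call was lost without WT1, KO2, WT3, KO3 or KO4 (adjusted p up to 0.317), and with WT4 and KO4 left out together (adjusted p 0.0843).

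Of 30 type I interferon response genes, 26 had higher estimates in knockout (median log2 fold change 0.13, adjusted p 0.0229, and adjusted p 0.802 with an estimated correlation), with Ifit1 at 12.3 ± 6.52 against 7.89 ± 1.6 CPM and Oasl2 at 45.0 ± 16.5 against 32.8 ± 10.2 CPM. Without KO1 the direction of this list turned (adjusted p 0.971), and the call was also lost without WT2, WT3, KO3 or KO4, with Xist as covariate (adjusted p 0.753) and with the TEC share as covariate (adjusted p 0.398). Of 18 NF-kB targets, 15 had higher estimates (median 0.10, adjusted p 0.0412, and adjusted p 0.782 with an estimated correlation), with Cd40 at 2.72 ± 0.992 against 1.51 ± 0.680 CPM. Its call was lost without WT1, KO1, WT2, WT3 or KO4 (adjusted p up to 0.387) and with Xist as covariate (adjusted p 0.273). Of 28 immediate early and dissociation response genes, 22 had lower estimates (median -0.09, adjusted p 0.0168, and adjusted p 0.782 with an estimated correlation). Egr1 had the smallest p of these; Fosb, another immediate early factor, was at 75.4 ± 38.2 against 99.0 ± 16.4 CPM. Its call was lost without KO1, WT2, KO2 or WT4 (adjusted p up to 0.560), with the TEC share as covariate (adjusted p 0.541) and with depth class as covariate, also added after seeing the data (adjusted p 0.464).

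The other 24 lists did not pass. Common lymphoid progenitor and early lymphoid genes had 13 of 24 members higher (adjusted p 0.995) and ILC precursor genes 7 of 19 (adjusted p 0.995), with Nfil3, a factor of innate lymphoid development, at 24.2 ± 3.48 against 18.4 ± 2.0 CPM. Adjusted p was also 0.995 for ILC3 and LTi cells, eosinophils, megakaryocytes and platelets, the unfolded protein and integrated stress response, cholesterol biosynthesis and steroid hormone synthesis. It was 0.0619 for mitochondrially encoded genes and 0.0898 for gate and lineage depletion markers. It was 0.204 for basophils and mast cells and for glycolysis and hypoxia, 0.239 for adhesion and trafficking, 0.272 for stroma and endothelium, and 0.359 for common gamma chain and STAT5 signalling. It was 0.370 for the heat shock response, for nuclear receptor and CBP/p300 coregulators and for neutrophils, 0.379 for replication-dependent histones and 0.412 for ILC1 and NK cells. It was 0.460 for p53 targets and apoptosis, 0.568 for stem cells and multipotent progenitors, 0.719 for Notch targets and 0.930 for dendritic and plasmacytoid dendritic cells. The median and the direction of the test differed in sign for stem cells, common lymphoid progenitors, ILC3 and LTi cells, eosinophils, megakaryocytes and cholesterol biosynthesis.

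Around Trerf1, where a knockout allele can carry flanking DNA of another strain, 163 tested genes started within 10 Mb, and 0 passed the threshold (edgeR), as did 0 of the 16188 others (Fisher's exact p 1). As 0 genes passed anywhere, the outcome of that test was fixed and it cannot speak to flanking DNA. At an unadjusted p under 0.05 there were 4 of the genes within 10 Mb (2.45%) and 317 others (1.96%, Fisher's exact p 0.565). The smallest p belonged to Cyp39a1, a hydroxylase of oxysterols (oxidised cholesterol), at 4.58 ± 0.987 CPM in knockout against 2.98 ± 0.624 CPM. Next were Vegfa at 0.516 ± 0.0951 against 0.292 ± 0.0268 CPM and Runx2os2, an antisense gene whose reads cannot be told from its partner's without strand, at 0.481 ± 0.281 against 1.01 ± 0.290 CPM.

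The first axis of variation did not follow the labels. Principal component 1, with 26.9% of the variance, placed KO1 to KO3 at 20.7, 29.8 and 25.6 and WT1 to WT3 at -10.6, -11.6 and -25.5, but WT4 at 2.13 and the library labelled KO4 at -30.4 (exact permutation p 0.200). Of the 100 genes with the largest weight on it, 58 were TEC transcripts, against 20.2% of the 2000 genes used. Relative to all counts, without scaling factors, TEC transcripts took 1893, 2083, 2686 and 1476 CPM in WT1 to WT4, and 1173, 1186, 1255 and 3075 in KO1 to KO4 (exact permutation p 0.314). Sense intronic transcripts, which lie within introns, took 292, 315, 346 and 247 CPM in WT1 to WT4 and 200, 192, 206 and 393 in KO1 to KO4 (exact permutation p 0.286). Components 2 and 3 held 21.9% and 21.5% of the variance, with exact permutation p of 0.600 and 1.

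**Figure D3:**
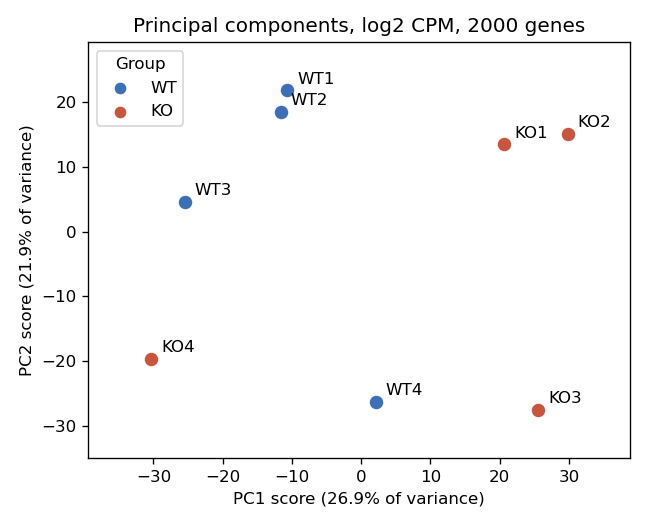
Scores of the 8 libraries on principal components 1 and 2 (axes labelled with their share of the variance; wild type blue, knockout red). KO1 to KO3 lie between 20.7 and 29.8 on component 1, and the library labelled KO4 lies at -30.4, beyond WT3 at -25.5.

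**Figure D4:**
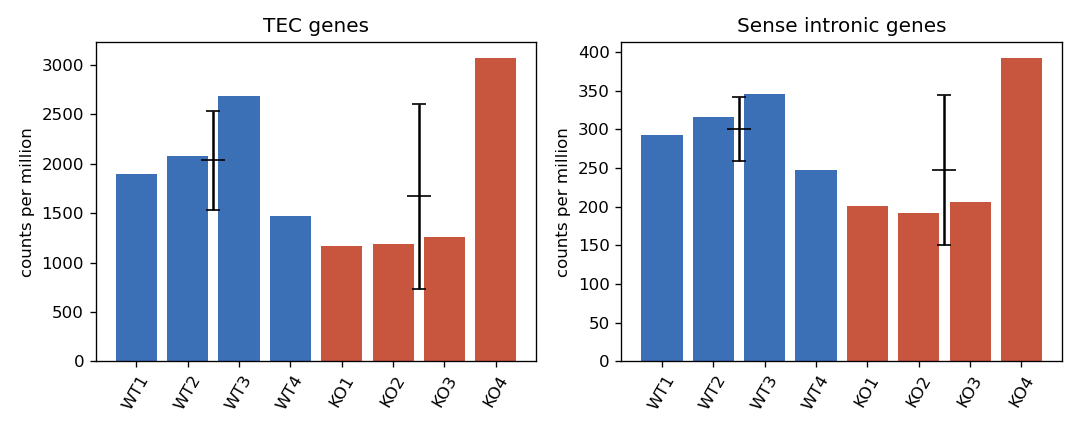
CPM (of all counts, without scaling factors) of TEC and sense intronic transcripts (vertical axes, from 0) in each library, with group means and SD in black. The library labelled KO4 has the highest value in both panels, 3075 and 393, and KO1 to KO3 the lowest 3.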

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

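Apart from the test of TEC transcripts inside and outside protein-coding genes, the explanations weighed here were tested only after the values they concern had been seen. Dixon's ratio, the gap divided by the range, was taken on log2 values, except for the component score, while the values printed here are not logged. In 8 of 174 groups of 4 libraries, 1 library stood apart from the other 3 past the ratio's 95% limit, where chance gives about 9. Of these 8, 7 were in the library labelled KO4: Trerf1 (22.1 CPM against 12.1 to 13.4, ratio 0.838), the total count (66515540 against 32821991 to 36184497, ratio 0.862), the TEC share (ratio 0.930), the sense intronic share (ratio 0.899), the antisense share (2066 CPM against 1709 to 1721, ratio 0.962), Kcnq1ot1, a long unspliced nuclear RNA (116 CPM against 27.3 to 31, ratio 0.911), and the score on principal component 1 (ratio 0.848). The other was Ccne2, an S phase cyclin, in KO3 (125 CPM against 88.0 to 89.4, ratio 0.954). Malat1 and Neat1, other long nuclear RNAs outside this test, did not share the pattern of Kcnq1ot1 to the same extent. KO4 over WT4 was 3.20 for Kcnq1ot1, 1.11 for Malat1 and 0.98 for Neat1. KO1 to KO3 over WT1 to WT3 was 0.36, 0.95 and 0.75 in the same order.

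Trerf1 was nearly equal in the libraries labelled WT4 and KO4. An exchange of these labels stays open. Alone it would not explain the near equality, since either library, taken as the knockout, would lie above KO1 to KO3 in Trerf1. WT4 lay 0.180 CPM above KO4, less than the SD of WT1 to WT3 (2.52 CPM), and both lay above all of KO1 to KO3 (up to 13.4 CPM) and below all of WT1 to WT3, so Trerf1 speaks no more for the labels as given than for an exchange. Other values go with an exchange, the last of them only in part. The split of WT1, WT2, WT3 and KO4 against KO1, KO2, KO3 and WT4 gave 29 genes, the most of the 35 splits, against 0 as labelled. The 11 genes other than Trerf1 that were lower in knockout without WT4 and KO4 were higher in KO4 than in WT4 (CPM without scaling factors). Principal component 1 placed KO4 (-30.4) on the side of WT1 to WT3, but WT4 (2.13) lay short of KO1 to KO3 (20.7 to 29.8). With 7 TEC transcripts among those 11 and 58 among the 100 genes of largest weight on the component, these values could also follow from a difference in unspliced RNA. RNA of both genotypes in both libraries would put Trerf1 between the groups, and it lay 57.5% and 56.4% of the way from the mean of KO1 to KO3 (12.8 CPM) to that of WT1 to WT3 (29.4 CPM) in WT4 and KO4. Only 1 protein-coding gene separated the remaining libraries past the threshold, too few to test this across genes. That gene, Gm20696, was at 28.1 CPM in WT4, between the groups (CPM without scaling factors). In KO4 it was at 54.4 CPM, above each of WT1 to WT3. Principal component 1 also placed KO4 beyond each of WT1 to WT3, where a mixture alone would not put it. A mixture with a difference in unspliced RNA on top was not tested, so a mixture also stays open. Whether Trerf1 counts follow the TEC share of a library on top of genotype is open too. A model of both fitted without WT4 predicted 24.0 CPM for it (observed 22.3; 29.3 from genotype alone), and fitted without KO4 it predicted 17.1 CPM for KO4 (observed 22.1; 12.7 from genotype alone), but each prediction rests largely on the other of these libraries, and exchanged labels would bring them closer as well. Without both libraries the slope of log2 Trerf1 on log2 TEC share was -0.33 ± 0.24 (SE), which does not show such a trend.

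TEC transcripts were lower in KO1 to KO3 than in WT1 to WT3 (ratio 0.54) and higher in KO4 than in WT4. Genotype as labelled would put KO4 below WT4, so as the whole cause it leaves the ratio of KO4 to WT4, 2.08, unexplained. That ratio is part of the pattern itself and rests on KO4 and WT4 alone. It is therefore no separate test of a genotype effect in the other libraries. Genotype with these labels exchanged stays open: WT4 at 1476 CPM lay below WT1 to WT3 but above KO1 to KO3, and KO4 lay above all of WT1 to WT3. Genomic DNA would add reads to silent genes as well, yet per kilobase of exon the difference between KO4 and WT4 in olfactory and vomeronasal receptor genes was 0.754% of that in TEC genes. A larger share of unspliced RNA in WT1 to WT3 and KO4 may account for part of the pattern: TEC transcripts inside a protein-coding gene on its strand had a KO4 to WT4 ratio of 2.31 (1530 genes), against 1.45 for the 1203 outside all protein-coding genes, and the ratio of KO1 to KO3 over WT1 to WT3 was 0.48 inside and 0.77 outside. The other 481, which overlap such a gene in another way, on its opposite strand included, stood nearer the outside ones, at 1.51 and 0.69, although reads of both strands were counted together. Whether such a share came from the cells or from RNA handling was not tested.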

How the results depend on the processing

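Alternatives that left out WT4 and KO4 together, changed the gene set, used the TEC share or depth class, or kept subsets of libraries by depth or Xist were chosen after seeing the data. The counts of 0 genes higher and 0 lower held under every alternative set in advance. The count within 10 Mb of Trerf1 was 0 under every alternative, which had to be so wherever no gene was called at all. Without WT4 and KO4, 12 genes were lower in knockout, and 7 with Xist as covariate as well; the Trerf1 log2 fold change was then -1.20 and -1.19 and passed (adjusted p 0.0473 and 0.0381). In the 3 deeper libraries 1 gene was higher and 1 lower, and in the 3 libraries without Xist 2 were higher and 2 lower; each set has 1 knockout library, assumed to vary like the wild type. Trerf1 stayed lower in knockout in each setting that tested it, from -1.11 to -0.78 with 1 library left out, with adjusted p from 0.0381 to above 0.99. The exact p of principal component 1 ranged from 0.143 to 0.857 over its alternatives.

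Of the 37 lists, 13 passed in the test set in advance, 8 with no count filter, 9 with Xist as covariate (7 of the 13 among them), 10 with the TEC share as covariate (9 of the 13), 0 with an estimated correlation, 0 with fry, 4 in the 5 shallower libraries, 7 in the 5 libraries with Xist, and 4 to 14 with 1 library left out. Of 312 values of the 13 lists under other settings, 195 kept their side of the threshold and direction, 113 lost the call and 4 turned: erythroid genes without WT1 (adjusted p 0.872, the highest with 1 library left out; lowest 9.15e-05), type I interferon genes without KO1 (0.971; lowest 5.24e-08), and in the 5 libraries with Xist mature B cell genes (0.944) and ILC2 genes (0.108). Of the log2 fold changes of the named genes other than Trerf1, 2257 values kept their direction without passing and 8 turned. Those 8 were Igha without KO4 (-0.027, with up to 1.94 without another library), and in the 5 libraries with Xist Ikzf3 (0.31), Klrg1 (0.22), Tnfsf11 (0.29), Prdm1 (0.28), Ier2 (0.24), Rhob (0.14) and Tspo (-0.048). The cause was not tested for any of these.

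The labels do not say what libraries of one number share. The deviations from group means of WT1 and KO1, WT2 and KO2, WT3 and KO3, and WT4 and KO4 correlated at 0.36, 0.31, -0.03 and 0.12. As 1 of these was not over 0.1, the numbers were not taken as pairs, though a day or preparation shared by some of them is not excluded. Setting the libraries numbered 1 and 2 against those numbered 3 and 4 gave 5 genes past the threshold, against 0 as labelled. At an unadjusted p under 0.05 (edgeR) that split gave 2084 genes, the most of any split, against 322 as labelled. This split was picked after its counts were seen, so it does not by itself show a difference by number. The main fit does not model the number. Across groups WT1, KO1, WT2 and KO2 correlated best with their own number, while WT3 did so with KO4 and KO3 with WT4. With the replicate block, 0 genes were higher and 0 lower (634 at an unadjusted p under 0.05), Trerf1 had log2 fold change -0.90, and 15 lists passed, the 13 among them. Genes at a few CPM rest on few counts in the 5 shallower libraries. The 72% recovered among simulated 2-fold changes covers all levels of the genes changed and no structure among libraries. It therefore does not measure recovery for such genes.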

Other observations

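The values of single marker genes here were chosen after they were seen, as were the counts over other splits of the libraries. Some basophil genes took similar levels in libraries of the same number, a likeness that was not tested. Prss34, a basophil protease, was at 13.6, 16.4, 94.4 and 220 CPM in WT1 to WT4 and at 14.5, 15, 75.8 and 249 CPM in KO1 to KO4. Mcpt8, another basophil protease, was at 5.05, 4.73, 24.8 and 36.4 CPM in WT1 to WT4 and at 5.66, 4.60, 13.7 and 48.2 CPM in KO1 to KO4. Cpa3, a mast cell and basophil protease, did not follow the number, at 66.7 CPM in WT3 and 30.2 CPM in KO3 and at 32.9 CPM in WT4 and 55.3 CPM in KO4. The median of the basophil and mast cell list relative to the mean of all libraries also differed within numbers, at 0.77 in WT3 and -0.01 in KO3. The erythroid gene Car1 was lower in libraries 3 and 4, at 73.6, 61.0, 9.75 and 2.26 CPM in WT1 to WT4 and at 35, 17.5, 1.41 and 7.36 CPM in KO1 to KO4. The early lymphoid genes Flt3 and Il7r spanned less, from 910 to 1339 CPM and from 269 to 415 CPM over the 8 libraries. Elane, a neutrophil granule protease, was at 17.0 CPM in the library labelled KO4, 4.70 CPM in WT4 and at most 1.28 CPM elsewhere.

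With WT4 and KO4 left out and protein-coding genes alone tested, 0 genes passed with edgeR and 884 had an unadjusted p under 0.05. Those with the smallest p on the lower side included Fosb, the chromatin and ubiquitin genes Ash1l and Herc1, and the biosynthetic enzymes Cad and Fasn, at log2 fold changes of -0.91 ± 0.15, -0.53 ± 0.09, -0.53 ± 0.09, -0.95 ± 0.17 and -0.75 ± 0.14 (SE, each adjusted p 0.583). On the higher side they included Slc7a7 at 0.82 ± 0.17, Tnfrsf13c at 0.49 ± 0.10 and Slpi at 0.63 ± 0.14 (adjusted p 0.602 to 0.604). Of the 20 protein-coding genes of smallest p on each side, KO4 and WT4 kept the direction for 1 on the lower side (Egr1, 111 against 112 CPM) and 6 on the higher side, among them Cym and Ifi214, by CPM without scaling factors. The genes named above went the other way, by little for Cad, Fasn and Tnfrsf13c: Fosb was at 78.2 in WT4 and 131 in KO4, Ash1l at 115 and 156, Herc1 at 84.5 and 108, Cad at 27.9 and 30.9 and Fasn at 50.8 and 55.8, and Slc7a7 was at 10.3 and 7.22, Slpi at 160 and 130 and Tnfrsf13c at 78.1 and 77.0. In the same 6 libraries, 86.7% of 789 TEC transcripts had lower estimates in knockout, against 45.1% of 12710 protein-coding genes.

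As the real split gave 0 genes, both overall and within 10 Mb of Trerf1, each of the 35 splits of the 8 libraries into groups of 4 gave at least as many by definition, which decides nothing about chance. The highest other split gave 29 genes, 0 of them within 10 Mb, where the highest other count was also 0. That split set WT1, WT2, WT3 and the library labelled KO4 against KO1, KO2, KO3 and WT4. The next, with 15 genes, set the libraries numbered 1 and 4, all with Xist, against those numbered 2 and 3, of which only KO3 has it. These libraries thus have a structure apart from their labels. Whether the 15 genes follow Xist or the library number was not tested. For the lists chance was not excluded: 7 of 35 splits gave at least the 13 of the real split, and the highest other gave 18. With WT4 and KO4 left out the 10 splits are too few for a share under 0.05; the real split gave 12 genes, 2 of the 10 splits gave as many, and the highest other, with 38, set the 3 libraries WT1, KO1 and KO3, which have Xist, against WT2, KO2 and WT3, which lack it.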
